A study of Gallus gallus with 2 samples.

How the data were processed

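Chromatin bound by CTCF was immunoprecipitated from chicken red blood cells labelled as 5 and 10 days old, and the recovered DNA was sequenced on an Illumina Genome Analyzer, per the labels' protocols. There was 1 library per age, and each came with 1 peak list. The cell type and age fields place both libraries in red blood cells, while the growth and treatment fields of the same labels describe density-purified, stimulated mononuclear blood cells. Groups were taken from the age field, and the labels do not say whether the ages are embryonic or after hatching, nor how many animals went into a library.

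The deposited lists have 6 columns and no header, and hold 1 peak per row with a sequence name, a start, an end and a score. The score is a whole number that the authors deposited for each peak, from 13 to 738 in the 5 day list and from 22 to 3381 in the 10 day list. Its meaning, any scaling to library size, the aligner, the peak caller, its threshold, any input or control library and the genome build are not given in the sources used here. Each library has its own list, but the sources do not say whether the lists were called separately. Every peak is 399 bp wide when the columns are read as a BED file, and positions are printed here with the first base counted as 1, so each printed start is 1 above the start in the file. The sequence names include unplaced sequence (Un_random), chromosome-specific random sequences and the linkage groups E22C19W28_E50C23 and E64. Read totals, and with them the depth of each library, are unknown. A score was used only to rank, filter or describe peaks within its own list, apart from 1 rank correlation over positions found in both lists. Peaks of equal score were ordered by sequence name, read as text, and then by start. A limit within a tie therefore kept some chromosomes before others, with Z last among the assigned chromosomes.

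The gene table at hand is on a different assembly (GRCg7b), so no peak was placed on a gene. The comparisons that need a matching genome or annotation were planned and not run. These were position relative to genes, the CTCF motif and the gene lists. Peaks are therefore named by position. The rule, set before the data were examined, names the 5 highest scoring shared peaks and the 5 highest scoring unmatched peaks of each list, and the 3 windows of 100 kb with the most peaks at each age. Peaks named outside this rule are marked as chosen after their values were seen.

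A peak was called shared when a peak of the other list overlapped it by at least 1 bp, and unmatched otherwise. Shares have exact Clopper-Pearson 95% intervals. The overlap was compared with 1000 random placements of the other list, in which each peak kept its width and its sequence, and a two-sided p was taken from them. The smallest p these placements can give is 0.002. Placements ran up to the last peak end on each sequence in either list, because sequence lengths of the build were not used here. Placements did not avoid assembly gaps or unmappable sequence. Scores of shared and unmatched peaks were compared within each list by a two-sided permutation test of the difference of medians, with 100000 resamples. These 4 p-values were adjusted together by the Benjamini-Hochberg method.

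Chromosomes were grouped, before the data were examined, into macrochromosomes (1 to 5), intermediate chromosomes (6 to 10), microchromosomes (11 and above; 28 is the highest numbered here), Z and unplaced sequence, the last including the linkage groups. Densities are peaks per Mb up to the last peak end. They are upper limits where a sequence extends beyond that peak. Ratios of counts and densities have exact conditional binomial 95% intervals. All intervals cover counting error within these 2 libraries. With 1 library per age, nothing measures the spread between animals or preparations, so no test compares the ages themselves, and peaks are not independent replicates.

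The overlap, density and score functions were tested on simulated data. With 60.4% of 5830 simulated 5 day peaks planted at 10 day positions, the overlap after removal of the chance share was 60.5%. Even placement of 17986 simulated peaks, drawn in proportion to the same spanned lengths, gave a micro- to macrochromosome density ratio of 1.00. This checks the calculation, not the effect of assembly gaps, unmappable sequence or true sequence lengths. Among 3000 simulated scores, a planted difference of 2 between medians was found as 2 (p = 0.0002, permutation test), and with none planted the difference was 0 (p = 1, permutation test). Alternatives changed the overlap rule, the score threshold, the length of the 10 day list, the peak width, the use of unplaced sequence and the random placement. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.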

Results

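CTCF is a zinc finger protein that binds DNA at insulators and at the bases of chromatin loops. Its binding was mapped by chromatin immunoprecipitation and sequencing in chicken red blood cells labelled 5 and 10 days, as 2 stages of development. The labels do not say whether the days were counted before or after hatching. Chicken red cells keep their nucleus, so chromatin can be recovered from them. The 5 day library gave 5830 peaks and the 10 day library 21358, which is 3.66 times as many. Scores in the 5 day list had a median of 22 (interquartile range 15 to 38), and scores in the 10 day list a median of 25 (23 to 29). The 10 day scores crowded against the lower limit of their list: 4118 peaks, 19.3% of the list, had the lowest score of 22, whereas 656 peaks (11.3%) of the 5 day list had its lowest score of 13. Leaving out unplaced sequence left 5123 and 20212 peaks, a ratio of 3.95. The depth of the libraries is unknown, and there was no replicate at either age, so the difference in peak number has no replicate check.

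The comparison of the 2 ages asks which CTCF peaks are listed at both. Most 5 day peaks were found again at 10 days, and most 10 day peaks had no 5 day counterpart. The latter follows largely from list length. The 5830 peaks at 5 days could overlap most of the 21358 at 10 days only if many overlapped several. Without an input library or the motif comparison, a listed peak is not shown to be an occupied site. Of the 5830 peaks at 5 days, 3358 were overlapped by a 10 day peak, a share of 57.6% (95% interval 56.3 to 58.9). Of the 21358 peaks at 10 days, 3372 were overlapped by a 5 day peak, a share of 15.8% (15.3 to 16.3). This left 2472 unmatched peaks at 5 days and 17986 at 10 days. Among 3318 pairs of overlapping peaks in which each was the nearest to the other, the starts lay a median of 38 bp apart (interquartile range 15 to 73), where the overlap itself keeps starts less than 399 bp apart. Random placement of the 10 day list put a peak on an average of 100.7 of the 5 day peaks and on at most 128 in 1000 placements, so the observed overlap was 33.3 times the random one (adjusted p = 0.002 by permutation of positions, the smallest the placements can give). Counted over the 10 day peaks, the same overlap was 33.3 times the random one (adjusted p = 0.002, permutation of positions), which is not an independent result. The factor depends on the placement: within 50 kb of each peak's own position, a placement chosen after the data were seen, it was 18.4 for 5 day and 18.2 for 10 day peaks. The shares depended on list length. When the 10 day list was cut to its 5830 highest scoring peaks, 45.5% of the 5 day peaks and 45.2% of the 10 day peaks were shared.

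The shared peaks were the higher scoring peaks of each list. At 5 days, shared peaks had a median score of 32 (interquartile range 21 to 49) and unmatched peaks one of 16 (14 to 21). At 10 days the medians were 43 (30 to 70) for shared and 24 (23 to 27) for unmatched peaks. Both differences passed the permutation test across peaks (adjusted p = 2e-05 each, from the smallest p that 100000 resamples can give). Recovery rose with score in both lists. Each list was divided by score into 5 parts of equal size. In the highest scoring part of the 5 day list 93.0% of peaks were shared (91.3 to 94.4), and in the lowest 23.8% (21.3 to 26.3). The 10 day list went from 56.7% (55.2 to 58.2) in its highest scoring part to 2.86% (2.38 to 3.40) in its lowest. At the top of the score range nearly all peaks were shared: 108 of the 109 peaks scoring at least 100 at 5 days, and 383 of the 387 at 10 days. Of the 100 highest scoring peaks, 48 at 5 days and 64 at 10 days lay on unplaced sequence, where repeated sequence could be shared too. Across the 3318 pairs the scores of the 2 ages had a Spearman rank correlation of 0.57, over peaks that are not independent replicates.

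**Figure D1:**
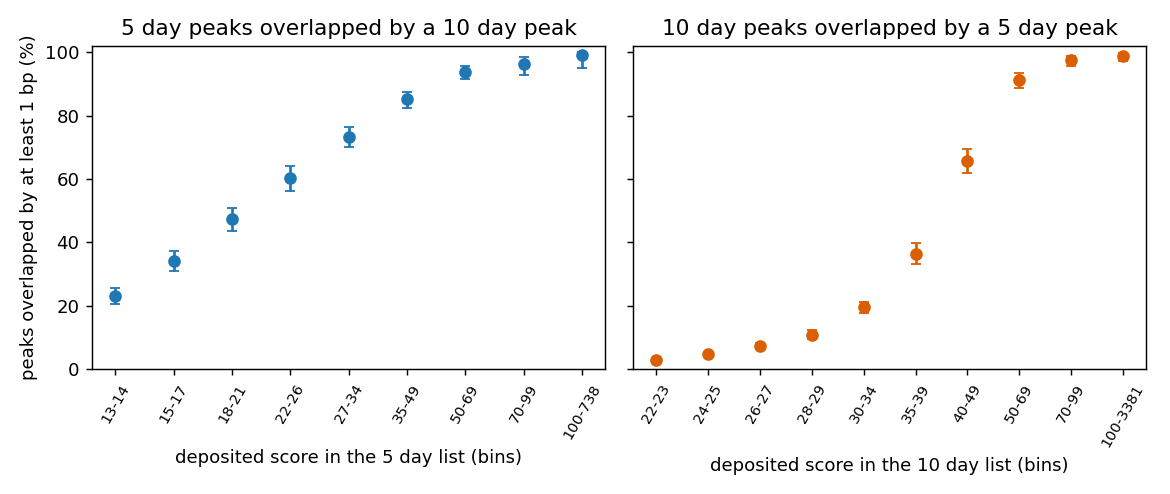
Share of peaks overlapped by at least 1 bp in the other list (vertical axis, percent) by deposited score (horizontal axis, bins), for the 5 day list on the left and the 10 day list on the right; points are shares and bars are exact 95% binomial intervals. The share rises from 23.0% to 99.1% in the 5 day list and from 3.0% to 99.0% in the 10 day list.

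Unmatched peaks were few only at high scores. At 10 days 515 of the 810 peaks scoring 35 to 39 and 227 of the 664 scoring 40 to 49 were unmatched. At 5 days 122 of the 821 peaks scoring 35 to 49 were unmatched. The limit of 50 used next was not fixed in advance. Scores of the 2 lists have no stated common scale, so it does not mark equal ranks. Among peaks scoring at least 50, 42 of 856 were unmatched at 5 days (4.91%, 95% interval 3.56 to 6.57) and 70 of 1481 at 10 days (4.73%, 3.70 to 5.93). Of these, 7 at 5 days and 28 at 10 days had a peak of the other list starting within 1 kb, and 30 of the 70 unmatched 10 day peaks lay on unplaced sequence. The highest unmatched 5 day peak, with a score of 132, was on chromosome 1 at 104451961 to 104452359. It lay between the 2 highest unmatched 10 day peaks, at 104451520 to 104451918 (score 545) and 104452404 to 104452802 (score 581), whose starts were 441 and 443 bp away. The next unmatched 5 day peaks were on chromosome 7 at 33088750 to 33089148 (score 87), on Un_random at 11503198 to 11503596 (score 79, with a 10 day peak 475 bp away), on chromosome 3 at 58210535 to 58210933 (score 76) and on chromosome 6 at 27346997 to 27347395 (score 75). The chromosome 3 and chromosome 6 sites had no 10 day peak starting within 54809 and 11720 bp of them. The remaining 3 of the 5 highest unmatched 10 day peaks were on Un_random, at 11507981 to 11508379 (score 103), 40699664 to 40700062 (score 100) and 35131665 to 35132063 (score 98). Each had a 5 day peak starting 638, 709 and 513 bp away, respectively. Away from any 5 day peak by more than 10 kb, the highest 10 day site on an assigned chromosome, chosen after its value was seen, was on chromosome 5 at 49513674 to 49514072, with a score of 70.

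Among assigned chromosomes, CTCF peaks were densest on the small ones. Chicken has a few large macrochromosomes and many gene-dense microchromosomes. At 5 days there were 3.37 peaks per Mb on macrochromosomes, 5.65 on intermediate chromosomes and 10.6 on microchromosomes. At 10 days the densities were 17.6, 21.0 and 28.3 per Mb. Unplaced sequence held 10.6 per Mb at 5 days and 17.1 at 10 days. With no input library, the part of these densities that is background is unknown. The microchromosomes thus held 3.13 times the macrochromosome density at 5 days (95% interval 2.94 to 3.33) and 1.61 times at 10 days (1.55 to 1.66). Over 27 autosomes spanning at least 1 Mb, density fell with chromosome length at both ages, with a Spearman correlation of -0.95 at 5 days and -0.89 at 10 days. Each had p = 1e-05 in a two-sided permutation test over chromosomes, the smallest that 100000 resamples can give, and chromosomes of 1 library are not replicates. Chromosome 2 had the lowest autosomal density at both ages (2.72 and 16.7 per Mb), and chromosome 26 the highest (20.2 and 45.3 per Mb).

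**Figure D2:**
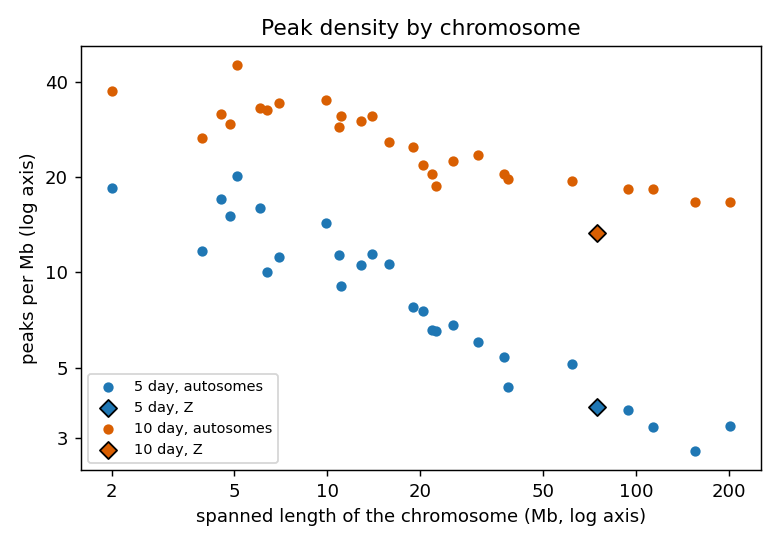
Peaks per Mb (vertical, log axis) against the length spanned by peaks (horizontal, Mb, log axis) for each autosome (circles) and Z (diamonds), at 5 days (blue) and 10 days (orange). Density falls with length at both ages, from 20.2 per Mb on chromosome 26 to 2.72 on chromosome 2 at 5 days and from 45.3 to 16.7 at 10 days.

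The longer 10 day list was not longer by the same factor everywhere. It held 5.21 times as many peaks as the 5 day list on macrochromosomes (95% interval 4.97 to 5.46), 3.72 times on intermediate chromosomes (3.45 to 4.02), 2.68 times on microchromosomes (2.54 to 2.83), 3.56 times on Z (3.11 to 4.08) and 1.62 times on unplaced sequence (1.47 to 1.78). Shared peaks are by definition almost the same positions in both lists, and their micro- to macrochromosome density ratio, counted over the 5 day positions, was 2.92 (2.68 to 3.18). Unmatched peaks can differ between the lists: the ratio was 3.41 (3.10 to 3.75) for the unmatched 5 day peaks and 1.45 (1.39 to 1.50) for the unmatched 10 day peaks. The 10 day ratio depended on how far down the list went. Among the 500, 1000 and 2000 highest scoring peaks on assigned chromosomes, limits chosen after the data were seen, it was 3.02 (2.46 to 3.70), 3.0 (2.60 to 3.45) and 2.63 (2.37 to 2.91). The 5 day values at these limits were 3.49 (2.86 to 4.25), 3.51 (3.05 to 4.04) and 3.31 (2.99 to 3.65). The intervals of the 2 ages overlapped at the first 2 limits and lay apart at 2000.

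**Figure D3:**
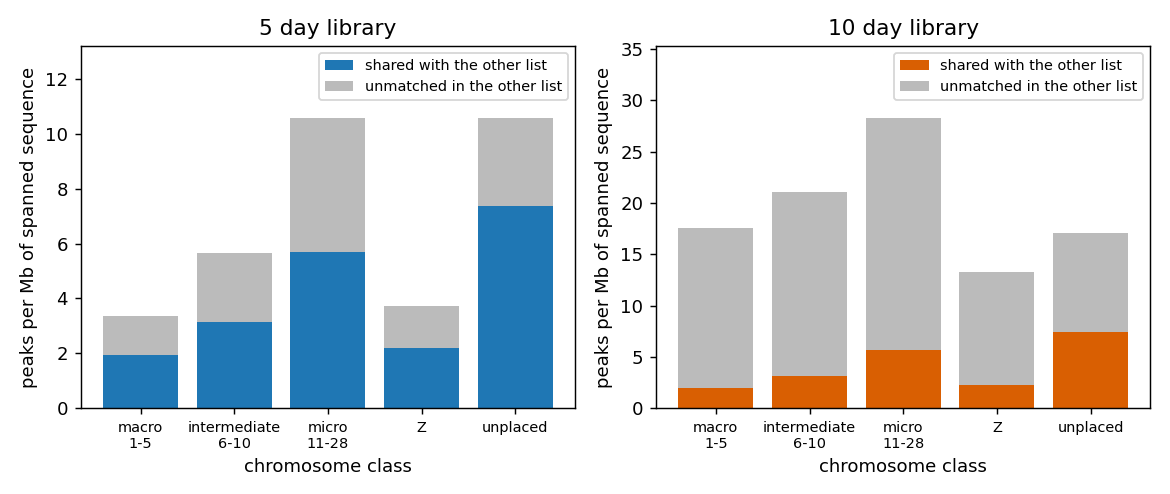
Peaks per Mb of spanned sequence (vertical axis) by chromosome class, at 5 days (left) and 10 days (right), with peaks shared with the other list coloured and unmatched peaks grey; the vertical scales of the panels differ. Shared peaks, almost the same positions in both panels by definition, stand at 1.94 per Mb on macrochromosomes and 5.68 on microchromosomes at 5 days, and the unmatched 10 day peaks reach 15.6 and 22.6 per Mb.

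The highest scores fell on unplaced sequence at both ages. Unplaced sequence held 12.1% of the 5 day list and 5.37% of the 10 day list, but 48 of the 100 highest scoring 5 day peaks and 64 of the 100 highest scoring 10 day peaks. All of these 48 and 64 peaks were shared. The 5 highest scoring shared 5 day peaks were on Un_random at 33878004 to 33878402 (score 738), 16903115 to 16903513 (score 720), 885537 to 885935 (score 674), 50618884 to 50619282 (score 613) and 15291951 to 15292349 (score 538). The first 4 of these were overlapped by the 4 highest 10 day peaks, with scores of 3381, 2941, 3017 and 3312. The next 10 day peak was on Un_random at 24682985 to 24683383 (score 2275). On assigned chromosomes, chosen after the values were seen, the highest 5 day peak was on chromosome 1 at 9648600 to 9648998 (score 355), where the 10 day peak scored 700. The next was on chromosome 13 at 18869456 to 18869854 (score 346), where the 10 day peak scored 350. The highest 10 day peak on an assigned chromosome was on chromosome 1 at 146895098 to 146895496 (score 816), and the 5 day peak at the identical position scored 198. Scores of the 2 lists have no stated common scale.

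Peaks also gathered in a few regions. The densest window of 100 kb was the same at both ages, on chromosome 1 from 104400001 to 104500000, with 26 peaks at 5 days and 28 at 10 days. In it, 25 of the 5 day and 23 of the 10 day peaks were shared, and scores reached 265 and 689. On chromosome 11, the window from 2600001 to 2700000 held 17 peaks at 5 days, of which 8 were shared, and 7 at 10 days, all shared. On Z, the window from 66200001 to 66300000 held 15 peaks at each age, of which 10 and 11 were shared. The second highest 10 day count was on chromosome 11 from 21300001 to 21400000, with 16 peaks at 10 days and 0 at 5 days. The third was on chromosome 22 from 2400001 to 2500000, with 15 and 5 peaks, level with the Z window at 10 days. The 10 day scores in the chromosome 11 window from 21300001 to 21400000 ranged from 22 to 38. Which genes lie in these windows was not analysed here.

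**Figure D4:**
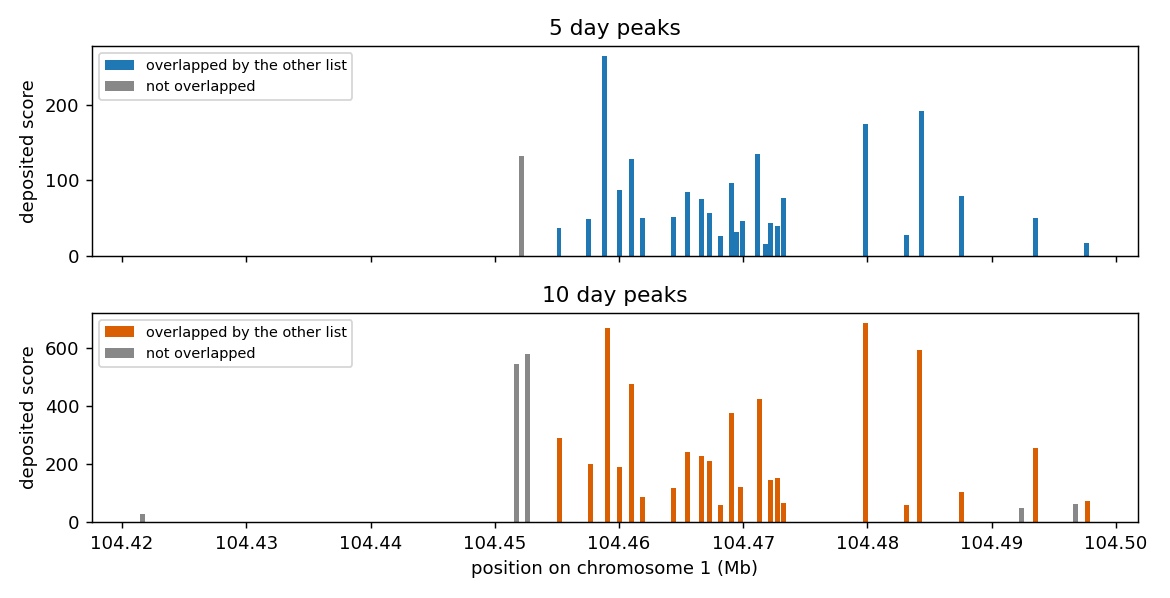
Peaks in the densest window, by position on chromosome 1 (horizontal axis, Mb) and deposited score (vertical axis, different scales), at 5 days (top) and 10 days (bottom); bars are drawn at the width of the peaks, coloured where the other list overlaps them and grey where it does not. The 26 peaks at 5 days and 28 at 10 days occupy matching positions, except 1 grey bar at 5 days and 5 at 10 days.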

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

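The overlap of the lists exceeded random placement under every overlap rule, score limit and width tried, from 10.5 times (peaks widened by 500 bp on each side) to 86.2 times (10 day list cut to as many peaks as the 5 day list) for 5 day peaks, and 18.4 times when peaks were placed within 50 kb of their own position. That placement, and leaving out unplaced sequence for scores and for recovery by rank, were chosen after seeing the data. The share of 5 day peaks found at 10 days lay between 45.5% and 76.2%, and the share of 10 day peaks found at 5 days between 14.2% and 45.2%. Overlap of 50% of either peak and of 50% of both are one rule here, because all peaks have the same width, and setting the width to 400 bp moved nothing in the 10 day share. The differences in median score were between 16 and 19 under all rules. Shares and score differences were judged by their test alone, and all 24 such alternatives kept its outcome, although 12 of the 18 shares lay outside the interval of the main share. Of the 21 other alternatives, judged by the interval of the main value or, for peak counts, by a change of 1.5 times, 12 moved. The upper 50% of the scores left 2915 and 10679 peaks by construction. Of the 5 parts by score, overlap of 50% of both peaks gave shared percentages of 91.0 and 20.8 in the highest and lowest at 5 days and 54.7 in the highest at 10 days. Widening gave 31.8 in the lowest at 5 days, and 59.4 and 4.35 in the highest and lowest at 10 days. Without unplaced sequence the lowest 5 day part was at 20.8 and the highest 10 day part at 51.5. The 10 day micro- to macrochromosome density ratio was 1.88 in the upper 50% of the scores and 2.12 at equal list length, and the cause was not tested. Tied scores at such limits were cut in order of chromosome name, which can shift these ratios by an unknown amount. No paired analysis was possible because each age has 1 library, and no library could be left out. Gene position, motif and gene list comparisons, with their alternatives, were not run for want of a genome of the files' build. Unknown read depth limits any statement on absence from a list.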

Other observations

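The tests below were chosen after the results were seen, except the count of dense windows of unmatched 10 day peaks, whose prediction was written first. They compare 2 libraries, and any difference between the ages remains an untested biological explanation throughout.

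Mitochondrial DNA held 3 peaks at 5 days, with scores of 13 to 15, and 1 at 10 days, with a score of 22. Peaks less than 1 kb from the previous start numbered 295 at 5 days and 789 at 10 days. A stretch of chromosome 11 from 21300001 to 21500000 held 29 peaks at 10 days, none of them shared, with a median score of 24 and a highest score of 38, and 1 peak at 5 days. The micro- to macrochromosome density ratio was 3.41 for unmatched and 2.92 for shared 5 day peaks, with overlapping intervals.

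The 17986 unmatched 10 day peaks were weak and differently distributed from the shared ones. A counterpart just outside the overlap rule accounts for few of them, since 1.52% had a 5 day peak starting within 1 kb. They did not lie along the chromosomes as the shared peaks do: their micro- to macrochromosome density ratio was 1.45 (1.39 to 1.50), against 2.91 (2.67 to 3.16) for shared 10 day peaks. Shared peaks were picked by overlap with the 5 day list, and they scored higher (median 43 against 24). The 10 day ratio also fell further down the list, and no comparison was made at equal score. The ratios therefore cannot decide whether the unmatched peaks are weaker sites of the same kind. Reads scattered evenly along the chromosomes do not account for all of the unmatched peaks, because 20 windows of 100 kb held 10 or more of them, where 1000 random placements gave at most 4. Those windows hold 1.31% of the unmatched peaks on assigned chromosomes. An uneven background, a mixture of background and weak sites, and sites gained by 10 days may each contribute, and read depth and an input library would be needed to separate them.

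The strongest peaks stood on unplaced sequence. Of the 100 highest scoring 10 day peaks 64% were unplaced (53.8 to 73.4), against 5.37% of the list. A candidate explanation is repeated sequence collecting reads from many copies. It needs the same positions to stand out in both libraries, and 100% of the unplaced peaks among the 100 highest were shared with the 5 day list, but strong CTCF sites would be shared too, so without the sequence these cannot be told apart.

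The Z chromosome ranked differently among the strongest peaks of the 2 libraries. Of the 1000 highest scoring peaks on assigned chromosomes, 26 were on Z at 5 days and 64 at 10 days, the highest ratio (2.46, 95% interval 1.54 to 4.05) among 27 chromosomes with at least 20 such peaks in the 2 lists together. That interval makes no allowance for the choice of Z as the highest of the 27. The density of Z relative to macrochromosomes was 0.54 (0.35 to 0.80) at 5 days and 1.24 (0.94 to 1.62) at 10 days. The limit of 1000 was the only one of 3 at which these intervals lay apart. The 500 highest gave 0.53 (0.28 to 0.92) and 1.19 (0.78 to 1.75), and the 2000 highest 0.80 (0.63 to 1.01) and 1.20 (0.99 to 1.45). The whole lists went the other way, with 1.11 (0.98 to 1.26) at 5 days and 0.76 (0.71 to 0.81) at 10 days. Peaks listed in 1 library only were few among the highest scores, so leaving them out could change little. The 1000 highest shared peaks included 28 on Z at 5 days and 63 at 10 days. They gave 0.58 (0.38 to 0.85) and 1.22 (0.92 to 1.60), and these intervals still lay apart. The intervals met for the 500 highest shared peaks, at 0.50 (0.26 to 0.90) and 1.20 (0.79 to 1.77), and for the 2000 highest, at 0.86 (0.69 to 1.08) and 1.17 (0.96 to 1.42). They met at these 2 limits for all peaks as well, so there the test cannot decide. Dense windows were left out in a further test: without windows of 10 or more peaks, 5 of them on Z, the values were 0.59 (0.39 to 0.86) and 0.96 (0.70 to 1.29) for the 1000 highest, 0.52 (0.26 to 0.92) and 0.83 (0.50 to 1.30) for the 500 highest, and 0.68 (0.52 to 0.87) and 0.86 (0.69 to 1.07) for the 2000 highest. The 10 day value fell inside the 5 day interval at 500 and 2000, as dense windows as the source would need. At 1000 it lay above that interval, but the intervals of the 2 ages no longer lay apart. The share of the dense windows therefore stays open. One hypothesis is that the cells of the libraries differed in Z copies per autosome set, as a different mix of sexes could give; in the lower 50% of the scores Z stood at 1.30 (1.09 to 1.54) at 5 days and 0.87 (0.80 to 0.95) at 10 days, the opposite order to the highest scores. The W random sequence held 4 peaks at 10 days and 0 at 5 days, too few to decide between lists that differ 3.66 times in length. A difference in Z copies was predicted to move the Z ratio the same way at every score, and the ratio did not move so. The 5 dense windows on Z were not left out of the whole lists or the lower 50%, however. They held 50 of the 279 Z peaks at 5 days and 57 of the 993 at 10 days. The labels used here do not give the sex of the cells, so whether such a difference contributed stays open.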
